A study of Rattus norvegicus with 12 samples.

How the data were processed

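Islet DNA from control and IUGR rats was profiled by HELP-tagging, with an HpaII and an MspI library for each of 3 replicate numbers per group, per the labels. The labels do not say whether replicates are separate animals or pools, so p-values from limma measure only the spread between these samples, which may be technical. Permutation and exact tests over CpGs or regions do not measure that spread. Positions are on the rat build rn6 (Rnor_6.0), per the submitters' processing notes. The aligner, tag counting, normalization and filters are not given in the sources used here.

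The deposited values are HELP scores, which the authors made for each CpG and replicate; the table of single CpGs has 3 control and 2 IUGR score columns, per the file headers. The labels number 3 IUGR replicates, and the sources used here do not say whether the third was left out or combined with another. Each IUGR column was taken as 1 replicate, so n = 2 counts columns. The columns were used by group because their names do not say which libraries they come from. The authors' p-value for each CpG was deposited without adjustment, and the test behind it is not given in the sources used here. The table of regions gives for each region the number of CpGs, the number called different, a list of scores per group, the mean difference, a p-value and a q-value, per the file headers. The order of replicates in those lists is not stated, so a region's replicates are known by their place only. The deposited q-values equal Benjamini-Hochberg values over 528 tests within 0.00067%, few more than the 512 regions listed.

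Of 4377 listed CpGs, 1 was a repeated row, which left 4376. Group means and differences were recomputed and matched the deposited values, within 0.1 for regions, whose scores are rounded; all differences here are IUGR minus control. The lists hold only CpGs with an absolute difference of at least 69.5 and regions with an absolute difference of at least 10.2, so sizes and shares describe the lists, not the genome. With 3 against 2 replicates, an exact permutation test of a single value has 10 splits and cannot give a one-sided p under 0.1.

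Before the data were examined, the design set limma on per-replicate levels as the test, with counts by direction, exact Clopper-Pearson 95% intervals and two-sided exact binomial tests. It assumed 3 replicates per group. Limma 3.58.1 (R 4.3.3) was fitted to scores without a block, with Benjamini-Hochberg adjustment at 0.05 over the listed CpGs or regions. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. Differences of medians and rank correlations had two-sided tests of 100000 permutations; 7 comparisons of higher with lower CpGs and regions were adjusted together. Intervals of median differences came from 1000 bootstrap draws of chromosomes. Neighbours were adjacent listed CpGs within 1000 bases, tested with 10000 permutations of direction within chromosome. The share of higher CpGs per chromosome was tested with a chi-square statistic and 10000 permutations of direction over all CpGs, across chromosomes. Exact intervals treat CpGs as independent, and depth is unknown, so no interval for counting error is given.

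The running number of the CpG table, which reaches 1797975, rises with chromosome and position and was used as the number of CpGs each chromosome could have listed, with borders midway between the neighbouring numbers. Chromosome Y, with 1 listed CpG, was left out of the chromosome test. Density was the number of CpGs the authors' table gives for a region per 1000 bases of its length. Scores were turned back from the arctangent scale and divided by the commonest score above 88 of their column, to see how many equal ratios of small whole numbers; no tag number was derived.

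The analysis was tested on simulated data. With the residual spread of the 4376 CpGs, limma recovered 44% of 100 simulated differences of 20 and 84% of 100 differences of 80, with 13 false calls among 4176 unchanged CpGs. With that of the 512 regions it recovered 89% and 100%, with 6 false calls among 312. The simulated scores were normal and unbounded, without selection on the difference or replicates all at 0. The false calls therefore do not give the error in the lists. The neighbour test passed 0.05 in 2.5% of 200 simulations of the 4376 CpGs without shared direction and in 100% of 50 with it. The chromosome test, on 4376 items over 21 equal chromosomes, passed for any chromosome in 6% of 200 even simulations. With 1 chromosome raised 1.5 times it passed in 100% of 200. It was not simulated for the 512 regions.

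Regions and CpGs named in the text were to be the 10 with the largest difference in each direction that have a gene assigned. The tables pair no gene names with positions and the gene table at hand is of another assembly, so genes were not assigned, and the rule was applied without that condition. Gene lists, named genes, location relative to genes, CpG islands and sequence were not analysed here. The direction of the scale was to be read from islands and gene starts; CpG density of regions took their place, chosen after the data were seen.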

Results

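DNA methylation was measured in pancreatic islets, the hormone-secreting cell clusters of the pancreas, from rats aged 2 weeks that had undergone intrauterine growth restriction (IUGR) and from control rats. HELP-tagging cuts genomic DNA at CCGG sites with HpaII, which methylation blocks, or with MspI, which cuts regardless of methylation, and sets the tags of the first enzyme against those of the other. The labels describe 12 libraries, 6 per group, in 3 replicate numbers with 1 HpaII and 1 MspI library each. The deposited tables analysed here hold scores for 3 control replicates and 2 IUGR columns, each taken as 1 replicate, on a scale that runs from 0 to 100. The tag depth behind each score is unknown. Directions are given as higher or lower scores in IUGR islets, because the sources used here do not name the methylated end of the scale.

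The listed single CpGs ran almost entirely in one direction. Most of them were at a score of 0 in control islets and at a high score in IUGR islets. The list held 4376 CpGs, of which 3991 scored higher in IUGR islets and 385 scored lower. The higher CpGs made up 91.2% of the list (exact Clopper-Pearson 95% interval 90.3% to 92.0%). Over the 3991 higher CpGs the mean score was 1.15 ± 0.144 (SD, n = 3) in control replicates and 80.9 ± 0.336 (SD, n = 2) in IUGR replicates. Over the 385 lower CpGs it was 82.4 ± 1.03 (SD, n = 3) in control replicates and 0.697 ± 0.659 (SD, n = 2) in IUGR replicates. These SDs are between replicate means over CpGs chosen on the same scores. They do not show how closely replicates agree at unselected CpGs.

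The two-sided exact binomial test of an even split, set in advance for equal groups, gave p of at most 1e-300, the smallest value kept. It is no test of the groups: with 3 against 2 replicates and scores mostly at 0, an even split is not the value expected without a difference, and CpGs are not independent replicates. All 4376 CpGs had adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment over the list. That is not independent evidence, since the list had been chosen on the same difference: the smallest absolute difference in it was 69.5 and the largest p in the authors' deposited table was 0.0501, without adjustment.

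At 3593 of the 3991 higher CpGs (90.0%) all 3 control replicates were at 0, and at another 386 exactly 1 control replicate was above 0. At 363 of the 385 lower CpGs (94.3%) both IUGR replicates were at 0. Where 3 replicates are all at 0, the spread of a CpG comes from the 2 IUGR replicates alone. Scores were also coarse: each replicate took between 140 and 283 distinct scores above 0, and the 10 commonest made up 36.1% to 50.3% of its scores above 0. Between 62.0% and 70.1% of them lay within 0.2% of an arctangent of a small whole-number ratio (numerator up to 3, relative to a common score), against at most 14.7% on 100 shifted scales. A score of 0 or near 100 can therefore rest on few tags. At 609 of the 3991 higher CpGs the IUGR replicates had the same score within 0.02, and these included 99 of the 100 higher CpGs with the smallest p in the authors' deposited table. Their median p in that table was 2.21e-09, against 2.06e-04 at the other 3382 higher CpGs.

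The CpGs with the largest differences went from one end of the scale to the other. On chromosome 9 the CpG at 121362866 was at 0 in all 3 control replicates and at 99.4 ± 0.602 (SD, n = 2) in IUGR islets. The CpG at 77495617 on chromosome 14 was at 0 in controls and at 99.2 ± 0.659 (SD, n = 2), and the CpG at 86264746 on chromosome 4 was at 0 in controls and averaged 99.2 in IUGR islets. The 10 highest differences ran down to 98.7, at 103551531 on chromosome 10. In the other direction, the CpG at 156142158 on chromosome 5 was at 97.7 ± 2.31 (SD, n = 3) in control islets and at 0 in both IUGR replicates. The CpG at 63484062 on the X chromosome was at 97.5 ± 2.15 (SD, n = 3) in controls and the CpG at 255345535 on chromosome 1 at 96.8 ± 1.77 (SD, n = 3), both at 0 in IUGR islets. A pair of CpGs on chromosome 12, at 8835558 and 9039694, had identical scores, 96.8 ± 1.61 (SD, n = 3) in controls and 0 in IUGR islets. A pair on chromosome 5, at 5056249 and 5215553, was also identical, at 96.2 ± 2.04 (SD, n = 3) in controls and 0 in IUGR islets.

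Listed regions leaned the same way as listed single CpGs. Of 512 listed regions, 489 scored higher in IUGR islets and 23 scored lower, so that 95.5% were higher (exact Clopper-Pearson 95% interval 93.3% to 97.1%). Over the 489 higher regions the mean score was 17.4 ± 0.833 (SD, n = 3) in control islets and 41.0 ± 0.159 (SD, n = 2) in IUGR islets. Over the 23 lower regions it was 58.6 ± 1.25 (SD, n = 3) in controls and 39.4 ± 0.188 (SD, n = 2) in IUGR islets. As for CpGs, these SDs are between means over a list chosen on the same scores and do not measure agreement outside it. A region held 4 to 14 CpGs, a median of 5, and spanned 107 to 12043 bases.

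The two-sided exact binomial test of an even split of regions gave p = 7.54e-115, with the same limit, that 50% need not be the share expected from 3 against 2 replicates without a difference. All 512 regions had adjusted p under 0.05 in limma, on a list that had again been chosen on this difference. With 1 IUGR value left per region, 401 higher and 19 lower regions passed without the first value and 410 higher and 14 lower without the second. The median absolute difference of the 23 lower regions was then 15.4 and 16.0, against 16.3 with both.

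**Figure D1:**
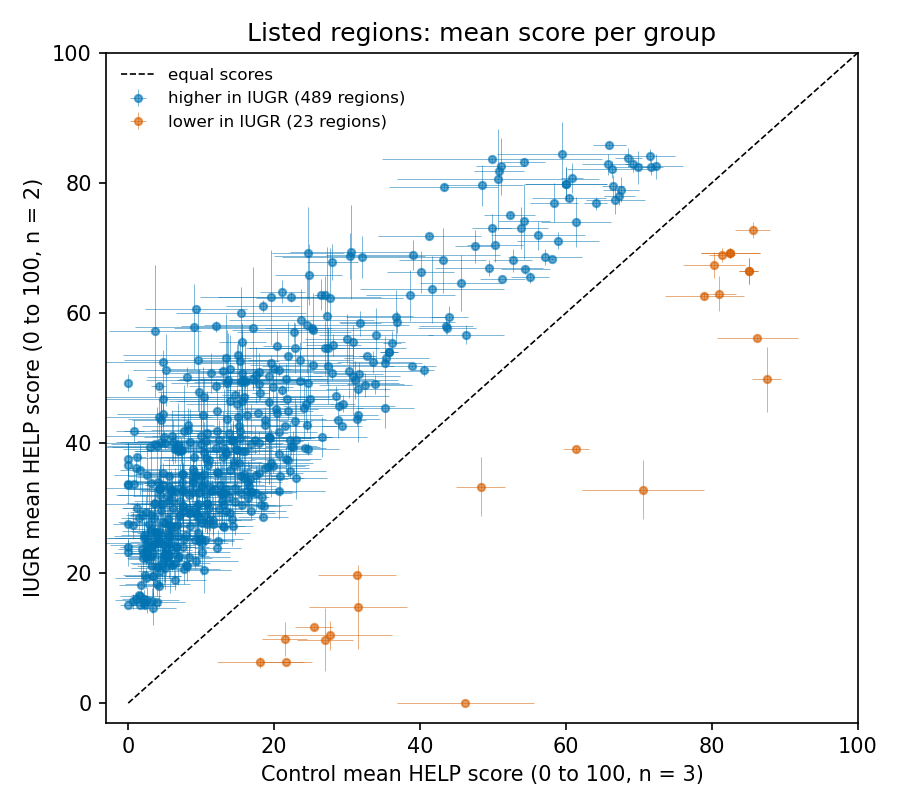
Each point is 1 of the 512 listed regions, with its mean HELP score in control islets (x axis, n = 3) and in IUGR islets (y axis, n = 2), both on the 0 to 100 scale; bars are 1 SD between replicates and the dashed line marks equal scores. The 489 regions higher in IUGR lie above the line, mostly at low control scores, and the 23 lower regions lie below it.

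The region with the largest rise lay on chromosome 8 from 75009569 to 75014932. Its mean score was 3.63 ± 6.29 (SD, n = 3) in control islets and 57.3 ± 10.1 (SD, n = 2) in IUGR islets, a difference of 53.6 (SE 5.45, limma adjusted p = 4.52e-04). On chromosome 15, the region from 42181160 to 42187096 went from 9.33 ± 7.0 (SD, n = 3) to 60.6 ± 0.212 (SD, n = 2). On chromosome 7, the region from 119726980 to 119729176 was at 0 in all 3 controls and at 49.3 ± 1.27 (SD, n = 2) in IUGR islets. Chromosome 10 held 3 of the 10 largest rises. The first, from 88590975 to 88594149, rose by 48.8 (SE 5.36, limma adjusted p = 5.44e-04). The next, from 102248112 to 102250104, rose by 47.6 (SE 4.93, limma adjusted p = 4.60e-04). The last, from 59116013 to 59120475, went from 4.20 ± 1.04 (SD, n = 3) to 48.8 ± 0.495 (SD, n = 2). The remaining 4 lay on chromosome 2 from 232507209 to 232509072, chromosome 4 from 81284250 to 81287236, chromosome 1 from 188095313 to 188098078 and chromosome 6 from 27343896 to 27345926, with differences from 44.6 to 46.0.

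The region with the largest fall lay on chromosome 2 from 60855335 to 60859520. It was at 46.2 ± 9.40 (SD, n = 3) in control islets and at 0 in both IUGR replicates (limma adjusted p = 6.52e-04). On chromosome 9, the region from 4051041 to 4051389 went from 87.6 ± 2.00 (SD, n = 3) to 49.8 ± 4.95 (SD, n = 2), and the region from 93546136 to 93546829 from 86.2 ± 5.55 (SD, n = 3) to 56.2 ± 0.283 (SD, n = 2). The region from 71126718 to 71127368 on the X chromosome went from 70.6 ± 8.35 (SD, n = 3) to 32.9 ± 4.60 (SD, n = 2). On chromosome 12 a pair of lower regions lay 131.4 kb apart. One, from 40200221 to 40201894, went from 61.4 ± 1.78 (SD, n = 3) to 39.1 ± 0.354 (SD, n = 2). The other, from 40067844 to 40068842, went from 27.0 ± 3.84 (SD, n = 3) to 9.75 ± 4.88 (SD, n = 2). The region on chromosome 15 from 15276009 to 15276690 went from 81.0 ± 2.41 (SD, n = 3) to 63.0 ± 2.69 (SD, n = 2), and the region on chromosome 20 from 8299277 to 8302566 from 27.6 ± 8.52 (SD, n = 3) to 10.4 ± 2.26 (SD, n = 2). Regions on chromosome 1 from 54517159 to 54517367 and from 55814749 to 55814957 had identical scores, 85.1 ± 1.30 (SD, n = 3) in controls and 66.5 ± 1.98 (SD, n = 2) in IUGR islets, and are counted here as separate regions. The nearest genes of these regions and CpGs were not analysed here.

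Sizes at single CpGs and over regions are not comparable, since the smallest listed difference was 69.5 for CpGs and 10.2 for regions. The median absolute difference was 78.3 at higher CpGs (95% bootstrap interval over chromosomes 77.9 to 78.6) and 80.7 at lower CpGs (78.2 to 82.4). Over regions it was 22.0 for higher (21.4 to 23.1) and 16.3 for lower regions (13.3 to 18.3). Within the lists, higher and lower CpGs differed in median size (two-sided permutation test, p = 3.10e-04, adjusted p = 5.42e-04 over 7 comparisons). So did higher and lower regions, by 5.70 (two-sided permutation test, p = 0.0107, adjusted p = 0.0149). These tests shuffled CpGs or regions as if independent and do not measure the spread between replicates. Both gaps moved with single replicates. The gap of 2.36 between CpGs was 0.118 (permutation p = 0.285) without IUGR replicate 1 and 0.945 (permutation p = 0.0448) without IUGR replicate 2, and 4.10 and 4.54 without control replicates 2 and 3. The gap between regions was 3.25 (permutation p = 0.136) without the first control value.

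Lower regions were shorter than higher regions and held their CpGs closer together. The 23 lower regions had a median length of 651 bases and 8.65 CpGs per kb, against 3099 bases and 1.67 CpGs per kb for the 489 higher regions. The median number of CpGs was 5 in both, so the contrast is one of the length over which the authors' CpGs were spread. Both differences had p = 1e-05 in two-sided permutation tests, the smallest that 100000 permutations give (adjusted p = 2.33e-05). Of the densest 20% of regions, 17 scored lower and 86 higher, against 6 lower and 403 higher among the others (two-sided Fisher's exact test, p = 1.61e-08). The 23 lower regions include 2 pairs with identical scores, and each copy was counted in these tests. Length went with the control score among them. Lower regions at mean control scores from 79.0 to 87.6 spanned 107 to 694 bases, and those from 18.1 to 31.5 spanned 349 to 4212 bases. Control scores were also higher in the densest regions, so these tests do not separate direction from control score. The median control score was 70.6 in lower and 12.4 in higher regions (p = 1e-05, adjusted p = 2.33e-05), and the median IUGR score 39.1 in lower and 37.6 in higher regions (two-sided permutation test, p = 0.808, adjusted p = 0.942). Part of the gap in control scores follows from the scale, on which a high control score leaves room to fall and a low one leaves room to rise. Both scores also enter the difference that sorts regions into higher and lower. Neither test is therefore independent of that grouping, and no difference in starting level can be drawn from them.

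Scores were higher where the CpGs of a region lay closer together. In 5 equal bins of regions ordered by CpGs per kb, mean control scores were 11.9, 14.6, 15.5, 17.6 and 36.5, and mean IUGR scores 37.8, 38.3, 37.3, 40.5 and 50.7. Spearman's rho of the mean score with CpGs per kb was 0.234 across 512 regions (two-sided permutation test, p = 1e-05, the smallest possible; Pearson's r with log10 density 0.509). Regions are not independent replicates. Without the densest 20% of regions rho was 0.0364 (p = 0.461), so the relation rested on them.

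**Figure D2:**
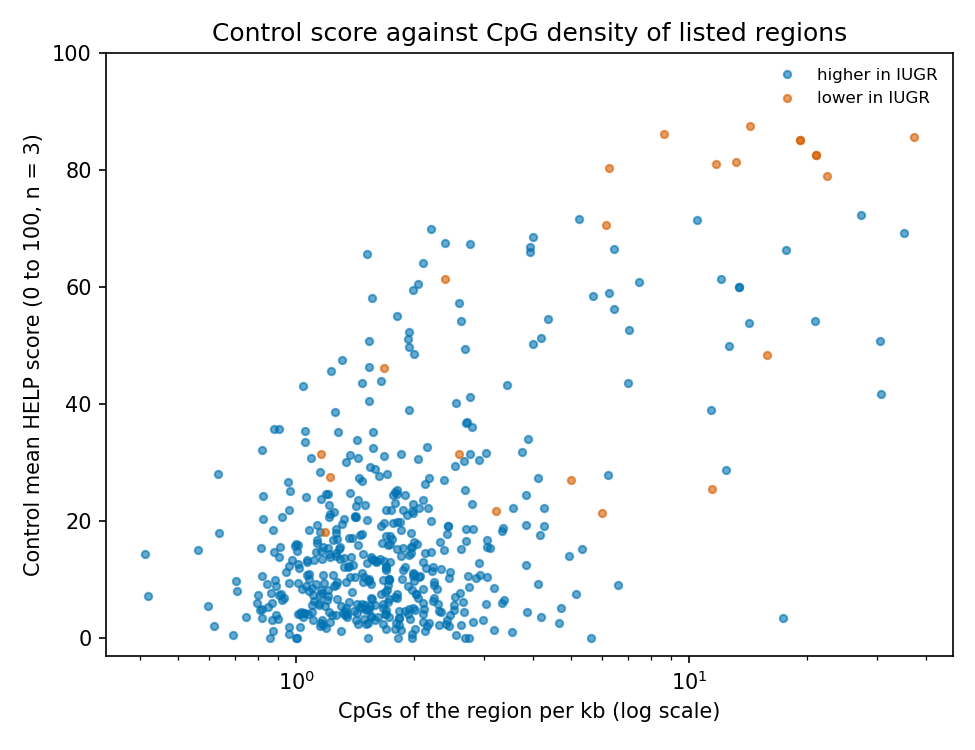
Each point is 1 of the 512 listed regions, with CpGs per kb of its length on a log axis and its mean HELP score in control islets (n = 3) on the 0 to 100 scale. The 23 regions lower in IUGR had a median of 8.65 CpGs per kb and the 489 higher regions 1.67 CpGs per kb.

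The listed CpGs were spread over all 21 chromosomes tested, close to the number of CpGs the authors' running number gives each chromosome. Observed over expected ran from 0.794 on chromosome 18 (105 CpGs) to 1.21 on chromosome 16 (166 CpGs). No chromosome passed the two-sided exact binomial test with Benjamini-Hochberg adjustment over 21 chromosomes, and 5 had unadjusted p under 0.05. Regions were nearly missing from the X chromosome, which held 1 of 512 regions where 18.9 were expected, a ratio of 0.0529 (95% interval 0.00134 to 0.293, adjusted p = 4.41e-06), but 172 of 4376 CpGs where 161.5 were expected. The share of X among regions (0.195%) was below its share among CpGs (3.93%; two-sided Fisher's exact test, p = 1.64e-07). The next lowest ratio for regions was 0.446 on chromosome 14 (9 regions, adjusted p = 0.0563). The share of CpGs that scored higher in IUGR ranged from 85.0% on chromosome 9 to 96.4% on chromosome 11 (permutation of direction across chromosomes, p = 2.00e-04, and p = 0.0053 with identical scores on a chromosome counted once).

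The expected numbers depend on the background. With the last listed position standing for chromosome length, 11 chromosomes passed for CpGs and 7 for regions. On X the ratio for CpGs then turned from 1.06 to 0.681 (172 CpGs where 252.7 were expected, binomial adjusted p = 2.86e-07). That for regions was 0.0338, so X was short of regions with both backgrounds and short of CpGs with this one. Neither background takes in how closely CpGs lie, and a listed region held at least 4. X had the fewest running numbers per kb, 0.417, with 0.534 on chromosome 2 the next lowest. Whether this spacing gives the shortage of regions was not tested.

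**Figure D3:**
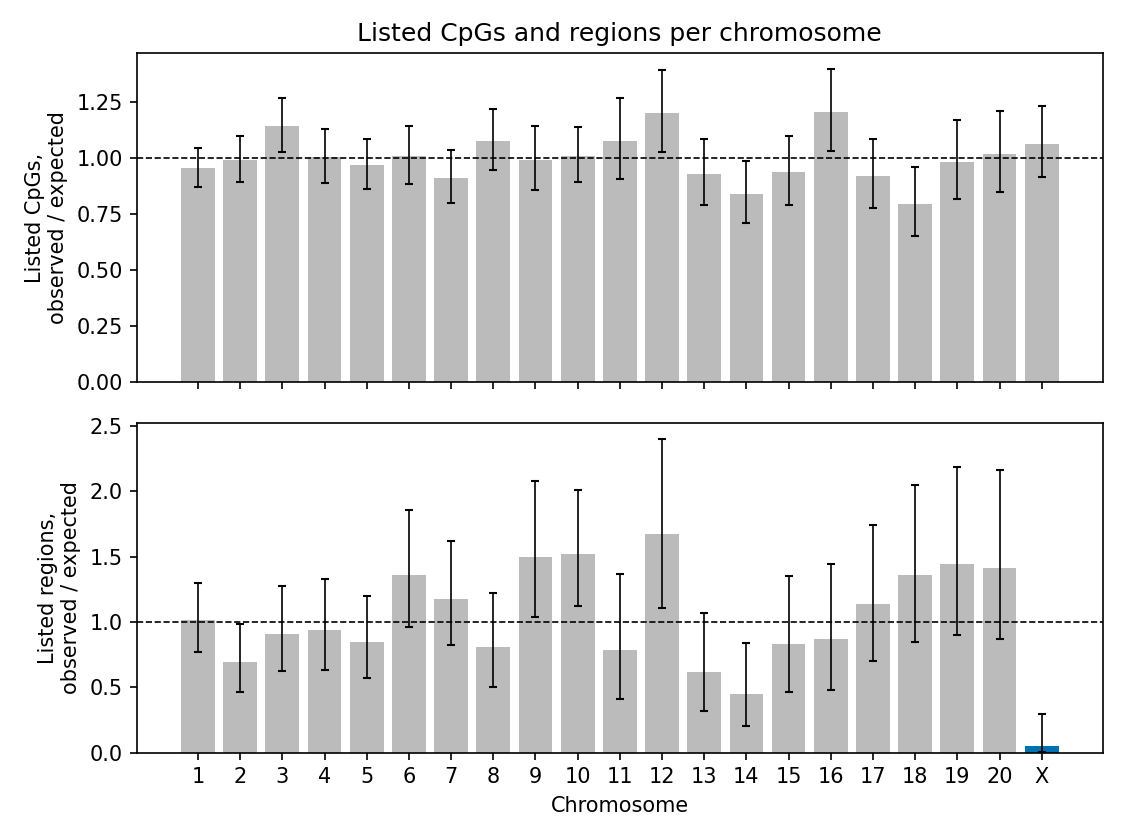
Bars give the listed CpGs (top) and regions (bottom) of each chromosome divided by the number expected from the authors' running number; error bars are exact 95% binomial intervals, the dashed line marks 1, and blue marks an adjusted p under 0.05. X held 1 region where 18.9 were expected and was the 1 chromosome past the test.

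Few listed CpGs lay inside regions, though more than unrelated lists would give. Of the 4376 CpGs, 174 (3.98%) lay inside 158 of the 512 regions, and 173 of the 174 had the direction of their region. With CpGs drawn at random from the list, 152 would have matched on average. The match was nearly fixed beforehand, since a region's score is a level over its own 4 to 14 CpGs. If the lists were unrelated, 6.61 CpGs would have been expected inside regions. The authors' counts give 1256 CpGs called different within the 512 regions, far more than the 174 listed singly. The cut behind that call is not given in the sources used here. In 148 cases the CpG was the first or last base given for the region.

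Neighbouring CpGs did not share a direction more often than chance gave. Of 40 pairs of adjacent listed CpGs within 1 kb, 35 had the same direction (87.5%), against 33.2 on average when directions were permuted within chromosomes (one-sided permutation test, p = 0.298). With 40 pairs and 91.2% of CpGs in the same direction, a modest tendency could have been missed, and its detection was not simulated.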

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

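Alternatives named here as added were chosen after seeing the data; the others were set before the data were examined. The share of higher CpGs stayed between 88.8% and 93.8% and that of higher regions between 95.3% and 98.0%, under a stricter p, larger differences, 1 CpG per 1 kb cluster, larger regions and autosomes only, and under added settings that counted identical scores once or adjusted the listed p-values over the whole running number (1898 CpGs passed). Every setting keeps the selection from 3 against 2 replicates, so this range does not bear on whether the groups differ. The 1898 CpGs passed on the authors' p-values, which coarse scores can make small. Among higher CpGs, 99 of the 100 smallest were at CpGs with IUGR scores equal within 0.02. Leaving out 1 replicate at a time, limma called 3709 to 3914 higher and 303 to 373 lower CpGs, 401 to 489 higher and 14 to 23 lower regions, and no difference changed sign; with 1 IUGR replicate left, it is assumed to vary like the controls. For CpGs the sign could not have changed. On a scale from 0 to 100, a difference of at least 69.5 cannot reverse when 1 replicate is left out. The unchanged sign of CpGs is therefore no evidence of stability. Region differences, of at least 10.2, were not fixed by the scale, but their list was chosen with all 5 replicates. With the replicate number as a block, 3627 higher and 332 lower CpGs passed. Whether the numbers pair the samples is not stated. The correlation of 0.0053 between same-numbered deviations of the 2 shared numbers cannot decide it. At 3593 CpGs all 3 control replicates were at 0, and at 363 both IUGR replicates were, so 1 group had no deviations there. No paired analysis was possible for regions because their score lists carry no numbers.

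Under the stricter p the median absolute difference was 79.2 for higher CpGs, 83.9 for lower CpGs and 23.8 for higher regions. Leaving out 1 replicate gave 78.7 to 80.7 for higher CpGs, 80.8 to 83.3 for lower CpGs, 21.3 to 22.5 for higher regions and 15.3 to 18.1 for lower regions. The added gap of medians was 0.118 to 4.54 between lower and higher CpGs and 3.25 to 7.15 between higher and lower regions, and missed the threshold without IUGR replicate 1 for CpGs and without the first control value for regions; the cause was not tested. The added density relation had rho from 0.180 to 0.304 in the other settings, but 0.0364 without the densest 20% of regions, and the cause was not tested. With chromosome extent as background, 11 chromosomes passed for CpGs and 7 for regions, and X turned from a ratio of 1.06 to 0.681 for CpGs; that background ignores how many CpGs each chromosome could list. The overlap stayed at 174 CpGs within 1 kb, and neighbours within 200 bases and 5 kb missed the threshold too. A coverage minimum, CpG islands by sequence, location and gene list settings were not run, since depth, sequence and genes were not used here. Unknown depth limits every score.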

Other observations

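All tests and summaries in this part were chosen after the data were seen. Some listed regions lay close together. Of 14 pairs of adjacent regions within 50 kb of each other, 13 shared a direction, in a list where 95.5% of regions scored higher; 1 of the 13, on chromosome 10 from 18903693 to 18905751 and from 18911263 to 18913321, had identical scores in all replicates and is not independent. The exception lay on chromosome 20, where a region from 8280546 to 8285683 scored 58.1 ± 0.289 (SD, n = 3) in control islets and 68.3 ± 0.141 (SD, n = 2) in IUGR islets, and the lower region from 8299277 to 8302566 began 13.6 kb further on. On chromosome 9, 4 pairs lay within 50 kb, among them the regions from 92898820 to 92903615 and from 92910868 to 92912207, which were 15.9 and 30.8 higher in IUGR islets. The region with the most CpGs called different, 8 of 13, lay on chromosome 10 from 59663911 to 59664334 and scored 50.7 ± 13.9 (SD, n = 3) in controls and 80.6 ± 7.71 (SD, n = 2) in IUGR islets. Chromosome Y had 1 listed CpG, at 2545764, at 0 in all 3 control replicates and at 76.3 in both IUGR replicates. Listed CpGs were next to each other in the running number 36 times, against 10.7 on average and at most 24 in 1000 random placements. The placements took every running number as equally open to listing, which is not known. The excess therefore does not show that differences between the groups cluster.

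The excess of higher scores in IUGR islets is the largest feature of both lists, and the lists were made from 3 control and 2 IUGR replicates. If a score above 0 fell on any replicate with one chance whatever the group, sites at 0 in 3 controls and above 0 in 2 IUGR replicates would outnumber the opposite pattern wherever that chance is low. A chance of 9.18% would give the observed 3593 against 363 CpGs, and since CpGs outside the list were not used here, the true chance is unknown and this explanation cannot be told apart from a difference between the groups. Among regions at a mean score of 50 or more, 80.9% still scored higher in IUGR (55 of 68, exact interval 69.5% to 89.4%). That argues against a single chance shared by all CpGs of such a region, although a mix of low and high CpGs within them stays open. The share was 96.9% (250 of 258) at mean scores under 25 and 98.9% (184 of 186) from 25 to 50. It was thus lowest at mean scores of 50 or more, the direction in which unequal replicate numbers would move it. The scale would move the share the same way, since high scores leave less room to rise. These shares do not separate the 2. An effect of growth restriction remains open and untested, as does a difference in depth between libraries.

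Identical scores at different places are a candidate sign of shared reads. In 9 pairs of regions all 5 scores were identical. The members of each pair shared a chromosome, in 8 pairs they had equal lengths, and shuffling each replicate's scores among regions gave 0 such pairs in each of 1000 shuffles. The pairs lay 5512 to 2089892 bases apart, and 2 of them were lower regions. Reads shared between near-identical copies of one sequence could give this; sequence was not used here and no biological explanation was tested. Among the 783 CpGs with at least 3 scores above 0, 126 fell in 55 sets with identical scores, and 22 sets lay on a single chromosome, against 2.81 on average when chromosomes were shuffled.

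A hypothesis for the scale is that its high end is the less methylated end, because CpG-dense sequence is usually unmethylated and HpaII cuts unmethylated sites. The rise of scores with density (rho 0.234 across regions, p = 1e-05) is consistent with it, in a test that could have given a fall, but density here counts the authors' CpGs per region length, and the relation rested on the densest 20% of regions, without which rho was 0.0364. If so, the listed differences may be mostly losses of methylation in IUGR islets.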
